A study of Caenorhabditis elegans with 6 samples.

How the data were processed

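Gene expression was measured in the nematode Caenorhabditis elegans, wild-type strain N2, at 2 points of larval life. Per the labels' protocols, animals that had been arrested after hatching were fed at the same time and kept at 20 °C. Active L3 larvae were picked by hand at 32 hours after feeding. Larvae in L3 lethargus, the sleep-like pause that accompanies the molt, were picked at 37 hours after feeding, on the basis that they neither moved nor fed. Each sample pooled 200 animals from 10 tubes of 20. Per the labels' protocols, 4 samples of each stage were collected and 1 of each was set aside for the quality of its RNA. The 3 remaining samples of each stage carry separate pool numbers, so p-values measure the spread between pools of animals. The labels do not say whether the pools were grown and picked on separate days.

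Per the labels' protocols, total RNA was converted to cDNA and amplified with the Nugen Ovation system before hybridization to the Affymetrix C. elegans Genome Array. The deposited table holds log2 expression values, which the authors made with RMA (background correction, normalization between arrays and summary of each probe set), per the submitters' processing notes. The version of RMA and the settings of its background step are not given in the sources used here. The lowest value of an array lay between 2.12 and 2.22, and a background correction that uses the GC content of probes is not excluded, which bears on how changes near background read. Amplification acts on every sample before labelling, so differences between probe sets of an array are not differences in transcript number. Changes of probe sets near background can be understated on this scale.

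The table held 22625 probe sets, of which 77 control probe sets were left out and 22548 were tested. The array annotation used here named 1 gene for 20766 probe sets, several genes for 887 and none for 895. Of the probe sets with 1 gene, 20701 matched the RefSeq table of assembly WBcel235 by gene identifier. Only probe sets with 1 gene were used to name a gene. No coordinates are given, because the table names no genome build. A gene with several probe sets was represented by the probe set with the highest mean over the 6 arrays, which gave 17118 genes. Among the genes named in the text, 15 had several probe sets, and for 5 of these the probe sets did not share a call. Probe set identifiers that end in _s_at or _x_at mark probes that can also match transcripts of related genes.

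The table holds no detection calls. The 24 probe sets for Bacillus subtilis control transcripts ranged from 2.42 to 5.73 on the log2 scale, with a median of 3.48, and served as a guide to background. The mean of 36.8% of the tested probe sets lay below the highest of these control values. Where a group mean of a called gene lay below it and the other group's lay above, the fold is given as a bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the gene's own value or the array's highest control, whichever was higher. This bound allows for background alone and not for the spread between arrays, so a fold with an array left out can lie below it. The number of arrays, 3 against 3, limits the precision of every difference.

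The design text names R/maanova with permuted p-values and a false discovery rate of 5%. That program was not run here. Lethargus was compared with L3 by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with the deposited values used without further normalization. P-values were adjusted by the Benjamini-Hochberg method over the 22548 probe sets, and an adjusted p of 0.05 or less was called. Changes are log2 differences, lethargus minus L3, with their standard errors (SE). All tests were two-sided.

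Gene lists were written from general knowledge of C. elegans before the data were examined, as were the tests, the first set of alternatives and the rule for the genes to be named. Lists were tested with camera in limma at its preset correlation of 0.01, with 1 probe set per gene and Benjamini-Hochberg adjustment over 29 lists. Member counts use that probe set and are also given adjusted over the list alone. Members called only on another probe set are named beside the counts. Gene symbols were matched exactly, since no older symbols were at hand, and some members asked for were therefore not measured. The named genes are the 10 largest rises and the 10 largest falls among called genes with a gene symbol whose arrays did not overlap between groups. To these were added up to 4 called members of each list with the largest change, or the member with the smallest p where none was called. A further 12 genes were named whatever their values: nlp-22, lin-42, nhr-23, mlt-10, nas-37, flp-11, flp-13, aptf-1, osm-11, lin-3, egl-4 and pdf-1. Genes named outside this rule are said to be so.

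The alternatives were a second quantile normalization, a common median, leaving out the dimmest part of the probe sets (the lowest of 3 equal parts by mean), eBayes with trend and robust (statmod 1.5.0), array weights, p-values from permuted labels, the replicate number as a block and leaving out each array in turn. For lists they also included an estimated correlation, the directional test fry, the mean of all probe sets of a gene and, leaving out probe sets marked _s_at or _x_at, which was planned for the cuticle collagens and added for the other lists after the data were seen. The analysis was tested on simulated data with 200 of 22548 probe sets changed in each of 5 runs. It recovered 67.8% of changes of 1 log2 unit, 98.2% of changes of 2 and 99.7% of changes of 3, and 5.85% of its calls were false. The changed probe sets were drawn at random, and no simulated array stood apart as L3 replicate 3 did. Recovery can therefore be lower for genes that varied more between arrays. On the real arrays elo-4 had a change of -2.19 and was not called (adjusted p 0.0747 from limma). With lists of 30 genes, 25 of 25 lists shifted by 0.3 were called and 0 of 75 lists without a shift. The simulated genes varied independently of each other, so this does not measure false calls of lists whose genes vary together. On the real arrays, splits that mixed the 2 stages called up to 12 lists.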

Results

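Lethargus is the quiet phase that C. elegans larvae enter at each molt, when they stop moving and feeding while a new cuticle is made. The study asked which transcripts differ between larvae in this sleep-like state and active larvae of the same stage. Expression was measured on 3 arrays of active L3 larvae and 3 arrays of larvae in L3 lethargus, each from a pool of 200 animals. The larvae in lethargus were also 5 hours further from feeding, at 37 against 32 hours, so age, phase of the molt and behaviour changed together. The arrays had median log2 values between 7.09 and 7.19, and no pair held the same values.

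Among the genes that rose in lethargus were 6 of 11 abu genes of the pharyngeal cuticle and 5 of 36 astacin proteases, and among those that fell were the molting genes mlt-9 and mlt-10. Adjusted over the list alone, 8 abu genes rose and 2 fell. The 8 include abu-2 and abu-3, outside the rule for named genes and within the range of the background controls on every array. The abu list was called by camera (adjusted p = 9.42e-09) but not with an estimated correlation (adjusted p = 0.469). The astacin list was likewise called (adjusted p = 0.0159) but not with an estimated correlation (adjusted p = 0.686). Probe sets for the abu genes abu-15, abu-10, abu-6 and abu-8, which encode repeat proteins of the pharyngeal lining, rose 32.1- to 47.7-fold, and 22.4- to 31.8-fold without L3 replicate 3. Those for abu-15, abu-6 and abu-8 can also match related genes, so these rises are not shown to be separate. The astacin metalloprotease gene nas-1, whose L3 mean lay within the range of the background controls, rose at least 14.1-fold. The molting gene mlt-10 and the zinc finger gene bed-3 fell 6.35-fold and 5.80-fold. Genes known to act in worm sleep, nlp-22 among them, were not called. In all, limma called 218 of 22548 probe sets at an adjusted p of 0.05 or less, 170 higher and 48 lower in lethargus. Of these, 155 were at least 2-fold higher and 42 at least 2-fold lower. The median log2 change was 1.93 among probe sets called higher and -2.0 among those called lower, against 0.016 over all probe sets. The called probe sets with 1 gene named 139 genes that were higher and 45 that were lower, and 78 of these 184 genes have only a sequence name. In 1761 probe sets all lethargus arrays lay above all L3 arrays and in 1482 all lay below, together 14.4% of those tested. The average share over all 10 splits of the arrays into 3 and 3 is 10%. The excess was not tested, and probe sets that vary together can give one.

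At an unadjusted p under 0.05, 1227 probe sets were higher and 1152 lower on the 6 arrays. Without L3 replicate 3, limma called 573 probe sets higher and 563 lower, and all 218 probe sets called on 6 arrays kept their call and direction. Leaving out any other array lowered both counts, to 89 higher and 1 lower without L3 replicate 1, 90 and 0 without L3 replicate 2, 75 and 0 without lethargus replicate 1, 86 and 1 without lethargus replicate 2, and 88 and 0 without lethargus replicate 3. Of the 15 named genes called lower, 15 stayed called without L3 replicate 3 and at most 1 without any other array. Of the 23 named genes called higher, 23 stayed called without L3 replicate 3 and 17 to 19 without another array. Array weights from limma gave 262 higher and 231 lower, and a variance trend with robust fitting gave 185 higher and 77 lower. The weights were lowest for lethargus replicate 3 (0.684), L3 replicate 3 (0.706) and lethargus replicate 1 (0.793).

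L3 replicate 3 stood apart from the other L3 arrays in its gene expression. On the first principal component, which held 50.1% of the variance, it lay at 0.82, against -47.7 and -40.9 for the other L3 arrays and 19.5 to 39.1 for the lethargus arrays. On the second, which held 21.1%, it lay at -41.9, against 7.25 and 3.95 for the other L3 arrays and -10.2 to 26.1 for the lethargus arrays. Genes of the molting and apical matrix list were lower there than in the other L3 arrays, with a median difference of -0.61, and those of the furrow collagen list with a median of -1.03. The abu genes were also lower there, with a median of -1.18 and 10 of 11 members below, whereas in lethargus their median was 1.75 above the other L3 arrays. Hedgehog-related genes, molting and timing regulators, glial and germline markers and cell cycle genes had medians there near or beyond those of lethargus. Calls of these lists therefore do not set lethargus apart from every L3 array. The median level of 43 sperm genes was highest there, at 7.04, against 5.15 and 5.31 on the other L3 arrays and 5.53, 6.28 and 6.01 on the lethargus arrays. Those of L3 replicates 1 and 2 and lethargus replicate 1 lay within the range of the background controls. Differences between 3' and 5' probe sets of 5 control transcripts, a guide to RNA quality, gave exact permutation p-values of 0.4 to 0.9 between stages, where 3 against 3 arrays cannot go below 0.1.

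**Figure D1:**
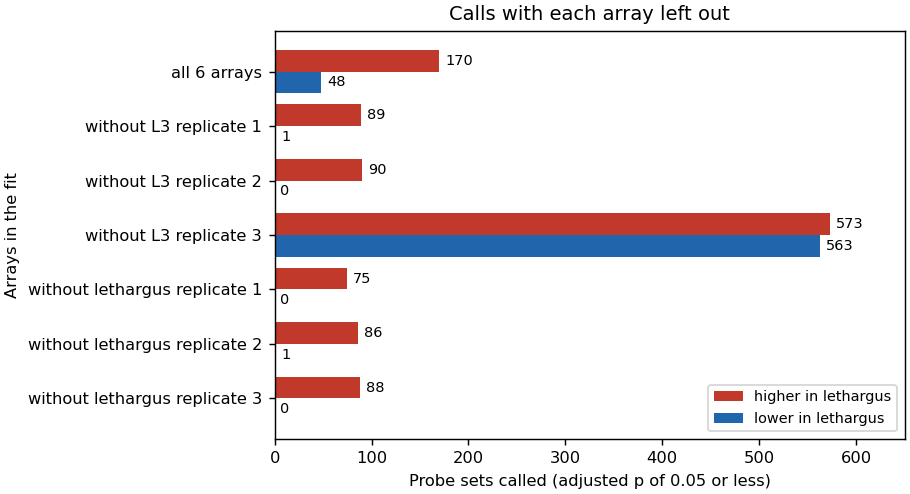
Number of probe sets called by limma at an adjusted p of 0.05 or less (x axis) with all 6 arrays and with each array left out (y axis), with bars for those higher (red) and lower (blue) in lethargus. With all arrays 170 were higher and 48 lower, and without L3 replicate 3 there were 573 and 563.

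The largest rises included those of probe sets for 4 abu genes, pqn-71 and dct-5. The log2 level of abu-15 rose from 7.04 ± 1.05 (SD, n = 3) to 12.61 ± 0.02 (n = 3), a change of 5.58 (SE 0.46), or 4.99 without L3 replicate 3. pqn-71, which encodes a protein rich in glutamine and asparagine, rose by 5.52 (SE 0.38) from 4.93 ± 0.52 to 10.45 ± 0.69. dct-5 rose by 5.49 (SE 0.28) from 6.36 ± 0.55 to 11.85 ± 0.27, and abu-10 by 5.41 (SE 0.37) from 6.71 ± 0.82 to 12.12 ± 0.13. The changes of nas-1, abu-6, piit-1 and abu-8 were 5.31, 5.21, 5.08 and 5.00. nspb-11 and nspb-10, members of a family of nematode-specific peptides, rose by 4.71 and 4.06. The L3 means of pqn-71, nas-1, piit-1, nspb-11 and nspb-10 lay within the range of the background controls, so the size of these rises and their order among the 10 are uncertain. Set against the highest control on each L3 array, these genes rose at least 31.1-, 14.1-, 25.5-, 9.67- and 12.4-fold. These bounds do not allow for the spread between arrays, and without L3 replicate 2 piit-1 rose 24.5-fold. The adjusted p-values of these 10 genes from limma ran from 0.000112 for nspb-11 to 0.00600 for piit-1. The probe sets of abu-15, abu-6, abu-8, nspb-11 and nspb-10 are marked as able to match related genes. Without lethargus replicate 1 the adjusted p of piit-1 was 0.0532.

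The largest falls were smaller than the largest rises. dbd-9 fell by 2.83 (SE 0.37), from 9.76 ± 0.68 (SD, n = 3) in L3 to 6.93 ± 0.47 (n = 3) in lethargus, with an adjusted p of 0.0178 from limma. mlt-10, named for the molting defect of its mutants, fell by 2.67 (SE 0.43) from 11.03 ± 0.70 to 8.37 ± 0.67, with an adjusted p of 0.0421. bed-3, a transcription factor gene needed for molting, fell by 2.54 (SE 0.39) from 9.74 ± 0.74 to 7.21 ± 0.48, with an adjusted p of 0.0379. The changes of mam-2, dos-2, lips-9 and mab-7 were -2.45, -2.39, -2.37 and -2.33, and the lethargus mean of dos-2 lay within the range of the background controls, which leaves a fall of at least 3.67-fold. Those of idpp-3, bus-5 and grl-10 were -2.26, -2.23 and -2.23, where bus-5 acts in making surface glycans and grl-10 belongs to the hedgehog-related ground-like family. In L3 replicate 3 all 10 genes were lower than the mean of the other L3 arrays, with differences from -0.64 for idpp-3 to -1.42 for mam-2. Leaving out any other array ended the calls of 9 of the 10, with adjusted p-values from 0.0717 to 0.212, while idpp-3 kept its call without L3 replicate 1 and without lethargus replicate 2. A dimmer probe set of mlt-10 had a change of -1.88 with an adjusted p of 0.175, and a dimmer probe set of mab-7 had -2.16 with 0.162. With the mean of all its probe sets, mlt-10 had an adjusted p of 0.0817, mab-7 had 0.0652 and mlt-9, a further molting gene, had 0.0573.

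**Figure D2:**
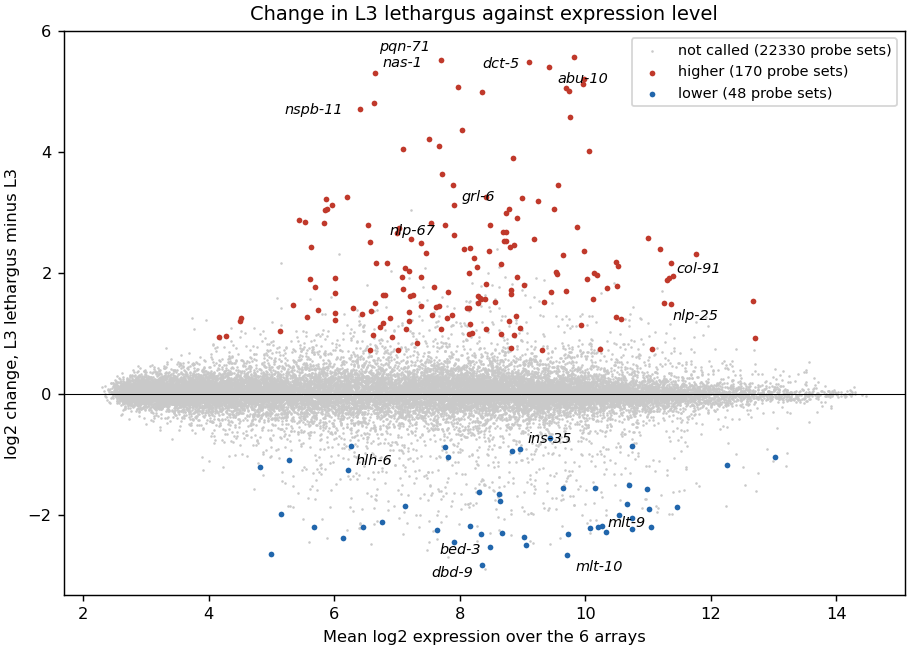
The log2 change of each tested probe set, lethargus minus L3 (y axis), against its mean log2 expression over the 6 arrays (x axis), with probe sets called higher in red and called lower in blue. The 170 rises reach 5.58 and the 48 falls reach -2.83.

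**Figure D3:**
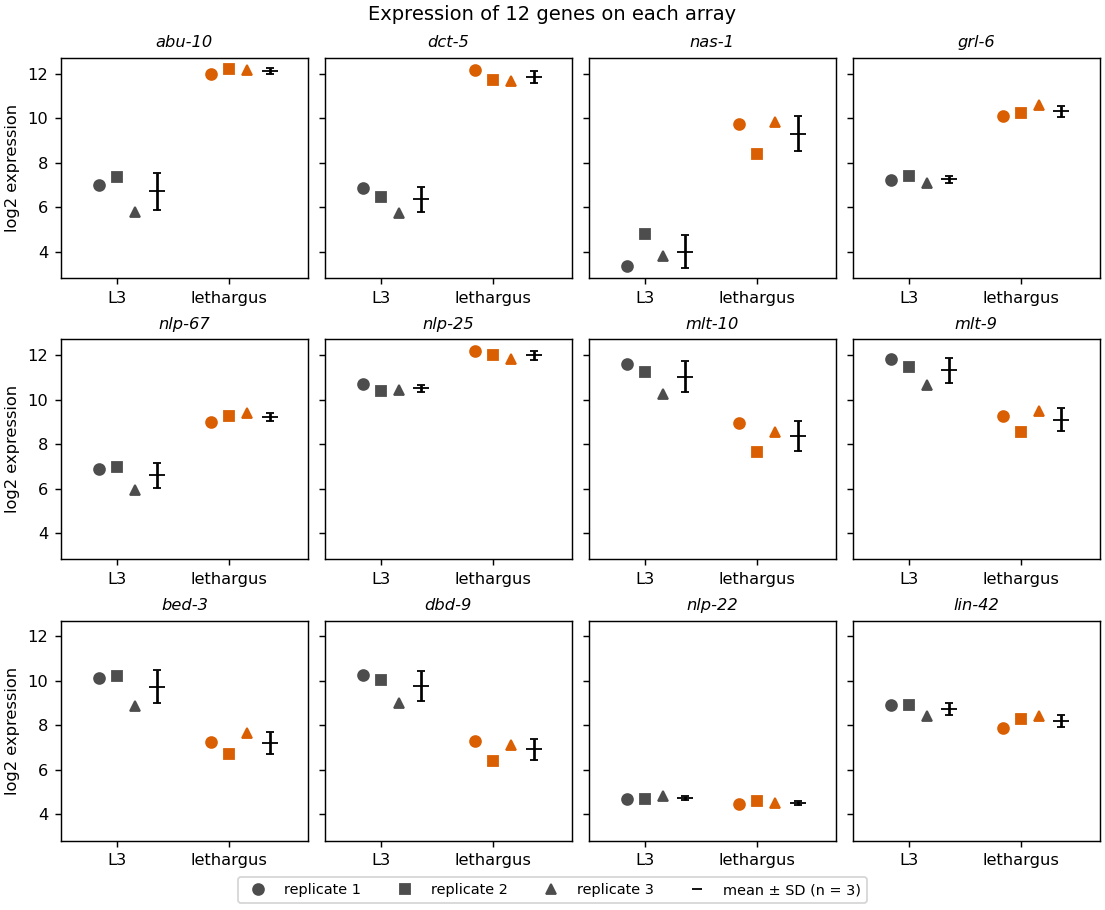
Log2 expression (y axis) of 12 genes on each array, with L3 in grey, lethargus in orange, a marker shape for each replicate, and bars for the mean ± SD (n = 3). abu-10 rose from 6.71 to 12.12, mlt-10 fell from 11.03 to 8.37, and nlp-22 had group means of 4.72 and 4.51.

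Genes for the lining of the pharynx were higher as a group. The list was higher in lethargus by camera (adjusted p = 9.42e-09), with adjusted p = 0.469 with an estimated correlation, in a range from 8.23e-11 to that value over 16 alternatives. Without probe sets marked as able to match related genes, an alternative chosen after the data were seen, it was 0.000276, with 5 of the 11 genes left, a median of 0.39 and abu-10 as the sole called gene. Of these 5, abu-2, abu-3 and abu-4 lay within the range of the background controls. Of 11 abu genes measured, 6 rose, 0 fell and 5 were not called, and adjusted over the list alone 8 rose and 2 fell. abu-11, abu-4, abu-12, abu-13, abu-14, abu-2 and abu-3 fall outside the rule for named genes and were chosen after their values were seen. abu-2 and abu-3, with changes of 0.39 and 0.65, were called higher only when adjusted over the list alone. Both lay within the range of the background controls on every array. abu-11 rose by 2.32, and abu-4, with an L3 mean within the range of the background controls, rose at least 2.79-fold. abu-12 and abu-13 went the other way, with -1.82 and -1.95 (adjusted p 0.0739 and 0.101). abu-14, already near 12 in L3, had 0.32 and 0.51 on its 2 probe sets. abu-10 was called on both of its probe sets, neither of them marked as able to match related genes, with 5.41 and 3.91. Every probe set of abu-6, abu-8, abu-11 and abu-15 is marked, so their rises are not shown to be separate. abu-4 was called on a marked probe set, while its unmarked probe set had 0.07 (adjusted p 0.967), with both means within the range of the background controls.

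Markers of pharyngeal muscle and gland were also higher as a group, though 0 markers rose by limma over all probe sets. Camera gave an adjusted p of 0.00330, with adjusted p = 0.450 with an estimated correlation, in a range from 0.00169 to that value over 16 alternatives, and fry gave 0.00682. Without probe sets marked as able to match related genes, an alternative chosen after the data were seen, the call ended, with 9 genes left, a median of 0.25 and an adjusted p of 0.233. Of 15 measured, 14 had a positive change with a list median of 0.41, and the sole called member, hlh-6, fell by 1.27 (SE 0.16, adjusted p 0.0166, and 0.0594 to 0.113 with any array other than L3 replicate 3 left out). hlh-6 encodes a transcription factor of the pharyngeal glands, and its lethargus mean lay within the range of the background controls. Adjusted over the list alone, 1 rose and 1 fell.

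Cuticle collagens, the main proteins of the body cuticle, moved in both directions. Of 145 measured, 3 rose and 3 fell, and adjusted over the list alone 5 rose and 9 fell. col-91 rose by 1.92 (SE 0.14) from 10.38 ± 0.18 to 12.29 ± 0.07 (SD, n = 3 each), and col-129 rose by 1.62, a call that ended without L3 replicate 1, lethargus replicate 2 or lethargus replicate 3 (0.0537 to 0.0565). col-153 fell by 1.78, and col-172 fell by 1.58. Leaving out any array other than L3 replicate 3 ended the calls of both (0.0915 to 0.234 and 0.0813 to 0.232). The list was not called (camera adjusted p 0.678), and its median of 0.07 and mean of -0.02 differed in sign. With a second quantile normalization the adjusted p of col-172 was 0.0530, in a range from 0.00558 to 0.232 over its 15 alternatives. The furrow collagens, which form the ring-shaped grooves of the cuticle, all had lower means in lethargus. Of 5 measured, 0 were called by limma over all probe sets or adjusted over the list alone, while 4 had an unadjusted p under 0.05. dpy-7 went from 11.74 ± 0.44 to 10.62 ± 0.67 (SD, n = 3 each), a change of -1.12 with an adjusted p of 0.288. The list was lower by camera (adjusted p = 0.000652), with adjusted p = 0.652 with an estimated correlation, in a range from 3.94e-06 to that value over 16 alternatives.

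Of 15 genes for collagen processing and folding, each taken by its brightest probe set, 1 rose and 0 fell, and adjusted over the list alone 1 rose and 2 fell. The gene that rose over all probe sets was mlt-7, which encodes a peroxidase that cross-links the cuticle, with a change of 1.78 (SE 0.20, adjusted p 0.00869), which lost its call without L3 replicate 2, lethargus replicate 1 or lethargus replicate 3 (0.0531 to 0.0558). A dimmer probe set of mlt-7 had 0.76 with an adjusted p of 0.130. bli-4, outside the rule for named genes and chosen after its values were seen, had 0.04 on its brightest probe set (adjusted p 0.987), while 1 of its 8 other probe sets rose by 1.25 (adjusted p 0.00715). The list was not called (adjusted p 0.928), and its median of 0.03 and mean of 0.06 were positive while the test pointed down. Without probe sets marked as able to match related genes, chosen after the data were seen, 8 genes were left and the list was higher, with an adjusted p of 0.0410 in a range from that value to 0.973 over 16 alternatives.

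Genes of molting and of the apical matrix, the extracellular coat under the old cuticle, were lower as a group. Camera gave an adjusted p of 1.07e-11, with adjusted p = 0.469 with an estimated correlation, in a range from 6.71e-13 to that value over 16 alternatives. Of 28 measured, 0 rose and 2 fell, and adjusted over the list alone 0 rose and 8 fell. The 2 were mlt-10 and mlt-9, which fell by 2.21 (SE 0.35, adjusted p 0.0388), and a second probe set of mlt-9 had -2.09 with an adjusted p of 0.0816. The call of mlt-9 ended with any array other than L3 replicate 3 left out (0.0915 to 0.198). nas-37, a protease needed to shed the old cuticle, had a change of -1.46 with an adjusted p of 0.415.

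Regulators of molting and of larval timing were lower as a list, with bed-3 as the sole member called on its brightest probe set. The list median against the other L3 arrays was -0.25 on L3 replicate 3 and -0.15 in lethargus. Camera gave an adjusted p of 0.0307, with adjusted p = 0.652 with an estimated correlation, in a range from 0.0102 to that value over 16 alternatives. Of 20 measured, 0 rose and 1 fell, and adjusted over the list alone 0 rose and 2 fell. lin-42, the worm counterpart of the clock gene period, had a change of -0.54 (adjusted p 0.380), and nhr-23, a nuclear receptor that drives molting, had 0.11 (adjusted p 0.953). nhr-41, outside the rule for named genes and chosen after its values were seen, had -1.05 on its brightest probe set (adjusted p 0.136). A dimmer probe set of nhr-41, with both means within the range of the background controls, was called lower with -1.21 (adjusted p 0.0444). The call of the list ended without L3 replicate 1 (0.254), without lethargus replicate 2 (0.129), without lethargus replicate 3 (0.119) and with the dimmest probe sets left out (0.121).

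Hedgehog-related and patched-related genes, many of them active in the epidermis, split into rises and falls. The list was lower by camera (adjusted p = 0.00264), with adjusted p = 0.851 with an estimated correlation, in a range from 8.51e-06 to that value over 16 alternatives. Of 80 measured, 4 rose and 2 fell, and adjusted over the list alone 12 rose and 28 fell. Against the other L3 arrays, the list median was -0.38 on L3 replicate 3 and -0.22 in lethargus. grl-6 rose by 3.07 (SE 0.16) from 7.25 ± 0.15 to 10.32 ± 0.24 (SD, n = 3 each), grl-4 rose by 2.58, and ptr-3, with an L3 mean within the range of the background controls, rose at least 5.35-fold, while grl-10 fell by 2.23. The bound for ptr-3 does not allow for the spread between arrays, and without lethargus replicate 3 it rose 4.69-fold. The call of ptr-3 ended without L3 replicate 1, L3 replicate 2, lethargus replicate 1 or lethargus replicate 2 (0.0585 to 0.198), and that of grl-10 ended with any array other than L3 replicate 3 left out (0.0813 to 0.128). grd-1, outside the rule for named genes and chosen after its values were seen, had -1.94 on its brightest probe set (adjusted p 0.317). A dimmer probe set of grd-1, with a lethargus mean within the range of the background controls, was called lower with -2.21 (adjusted p 0.0323), a size that is uncertain for that reason.

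Astacin metalloproteases, secreted enzymes that process cuticle and matrix proteins, included nas-1, which was among the 10 largest rises. The L3 mean of nas-1 lay within the range of the background controls. Camera gave an adjusted p of 0.0159, with adjusted p = 0.686 with an estimated correlation, in a range from 0.00388 to that value over 16 alternatives. Of 36 measured, 5 rose and 0 fell, and adjusted over the list alone 7 rose and 2 fell. Beside nas-1, nas-27 rose by 3.24 (SE 0.36), toh-1 by 2.43 (SE 0.21) and nas-5 by 2.24 (SE 0.20). The call of nas-27 ended without L3 replicate 1 or any lethargus array (0.0501 to 0.0525). toh-1 was called on 2 of its 3 probe sets, and the third, the dimmest, had 0.58 with an adjusted p of 0.448. The call of the list ended without L3 replicate 3 (0.280), with the dimmest probe sets left out (0.0576) and with array weights (0.0855).

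Genes with known roles in worm sleep were not called, which does not show that they were unchanged. Of 36 measured, 0 rose and 0 fell by limma over all probe sets or adjusted over the list alone, and 5 had an unadjusted p under 0.05. The list was not called (adjusted p 0.548). nlp-22, which encodes a neuropeptide of the RIA neurons, was at 4.72 ± 0.10 in L3 and 4.51 ± 0.08 in lethargus (SD, n = 3 each). Both means lie within the range of the Bacillus subtilis controls, a signal at which this array says little about nlp-22. aptf-1, a transcription factor gene of the sleep neuron RIS, was likewise within that range, with a change of -0.42 (adjusted p 0.573). The peptide genes flp-11 and flp-13 had changes of -0.06 and 0.06, the Notch ligand gene osm-11 had 0.01 and the EGF gene lin-3 had 0.45 (adjusted p 0.288). The kinase gene egl-4 had 0.05 and the arousal peptide gene pdf-1 had 0.29. The member with the smallest p, the adenylyl cyclase gene acy-4, had 0.61 (SE 0.15, adjusted p 0.155).

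Neuropeptide genes were mostly without calls. Of 49 neuropeptide-like protein genes, 1 rose and 0 fell, in both the count over all probe sets and that adjusted over the list alone. It was nlp-67, with a rise of 2.62 (SE 0.28) from 6.60 ± 0.57 to 9.22 ± 0.19 (SD, n = 3 each) and an adjusted p of 0.00753, which was 0.0522 without lethargus replicate 2 and 0.0517 without lethargus replicate 3. Of 25 FMRFamide-like peptide genes, 0 were called by limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05. flp-10 had the smallest p of these, with 0.44 (adjusted p 0.457). Of 24 insulin-like peptide genes, 0 rose and 1 fell in both counts, the one adjusted over the list alone included. It was ins-35, which fell by 0.91 (SE 0.12, adjusted p 0.0190, and 0.0635 to 0.127 with any array other than L3 replicate 3 left out). None of these 3 lists was called (adjusted p 0.191, 0.548 and 0.238). Without L3 replicate 1 the neuropeptide-like list had 0.0199, and without L3 replicate 3 the insulin list had 0.0379. Over their 16 alternatives the adjusted p ran from 0.0199 to 0.999 and from 0.0379 to 0.962.

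Antimicrobial peptide genes of the epidermis were higher as a group. Camera gave an adjusted p of 0.00205, with adjusted p = 0.450 with an estimated correlation, in a range from 0.000276 to that value over 16 alternatives. Of 18 measured, 1 rose and 0 fell, and adjusted over the list alone 4 rose and 1 fell. nlp-25 rose by 1.50 (SE 0.15) from 10.50 ± 0.17 to 11.99 ± 0.20 (SD, n = 3 each), with an adjusted p of 0.00679.

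Germline markers were slightly higher and cell cycle genes slightly lower as lists, with 0 members called by limma in either. Against the other L3 arrays, germline medians were 0.19 on L3 replicate 3 and 0.20 in lethargus, and cell cycle medians -0.31 and -0.24. Camera gave the germline list 0.00510, with adjusted p = 0.686 with an estimated correlation and a range from 0.00174 to that value over 16 alternatives. It gave the cell cycle list 0.00205, with adjusted p = 0.851 with an estimated correlation and a range from 4.27e-05 to that value. Of 37 germline markers, 31 had a positive change with a median of 0.18, and 3 had an unadjusted p under 0.05. pgl-3 had the smallest p, with 0.52 (adjusted p 0.373). Of 30 cell cycle genes, 24 had a negative change with a median of -0.15, and 7 had an unadjusted p under 0.05. cdk-1, the mitotic kinase gene, had -0.55 (adjusted p 0.210). Adjusted over the list alone, 0 members of either list were called. The germline call ended without L3 replicate 2 (0.109) and without lethargus replicate 1 (0.117), and the cell cycle call without L3 replicate 1 (0.0534) and without lethargus replicate 2 (0.258).

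Sperm genes were not called on 6 arrays. Of 43 measured, 38 had a positive change, 0 were called by limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05. The list had an adjusted p of 0.400, and fog-3, a gene that commits germ cells to sperm, had 0.29 (adjusted p 0.409). Without L3 replicate 3, the array with the highest sperm gene levels, the list was higher in lethargus with an adjusted p of 8.92e-09, and with array weights it had 0.00681. Over 16 alternatives the adjusted p ran from 8.92e-09 to 0.962.

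Glial markers were lower as a list of 7, with a median of -0.17 and 0 members called by limma. Their median against the other L3 arrays was -0.39 on L3 replicate 3 and -0.27 in lethargus. Camera gave an adjusted p of 0.0343, with adjusted p = 0.839 with an estimated correlation, in a range from 0.00756 to that value over 16 alternatives. daf-6, a patched-related gene of sensory glia, had -1.65 (adjusted p 0.179, and 0.0221 without L3 replicate 3), and adjusted over the list alone 0 rose and 1 fell. Of the 7, 2 had an unadjusted p under 0.05. The call ended without L3 replicate 1 (0.254), L3 replicate 2 (0.0570), lethargus replicate 1 (0.0681) or lethargus replicate 2 (0.0778), and with the dimmest probe sets left out (0.0691).

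Markers of the other tissues showed no call. Among 22 neuronal, 14 epidermal and seam, 20 body wall muscle and 29 intestinal markers, 0 were called by limma, also adjusted over the list alone. At an unadjusted p under 0.05 there were 0, 4, 0 and 5 of them. The lists had adjusted p-values of 0.705, 0.962, 0.928 and 0.548. Their members with the smallest p were ric-19 with 0.34 (adjusted p 0.572), eff-1 with -0.37 (0.290), tni-3 with 0.14 (0.844) and the yolk gene vit-4 with 0.77 (0.223), whose means both lay within the range of the background controls.

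Genes for protein synthesis and metabolism were not called. Among 62 ribosomal protein genes, 39 of oxidative phosphorylation and 15 of glycolysis, 0 were called by limma, also adjusted over the list alone, with 1, 0 and 1 at an unadjusted p under 0.05. Their medians were -0.03, 0.02 and -0.001, and their adjusted p-values 0.183, 0.928 and 0.928. rpl-41.2 had -0.39 (adjusted p 0.377), clk-1 0.24 (0.634) and hxk-1 0.49 (0.429). Without lethargus replicate 1 the ribosomal list was lower, with an adjusted p of 0.00567, in a range from that value to 0.962 over 16 alternatives. Of 19 genes of fatty acid synthesis and desaturation, 0 were called over all probe sets and 3 had an unadjusted p under 0.05. Adjusted over the list alone, 0 rose and 1 fell. This was elo-4, a fatty acid elongase gene, with -2.19 (SE 0.41, adjusted p 0.0747 over all probe sets). Its adjusted p was 0.00459 without L3 replicate 3, and the list had 0.284. Without probe sets marked as able to match related genes, chosen after the data were seen, 13 genes were left and the list was lower, with an adjusted p of 0.0410 in a range from that value to 0.959 over 16 alternatives.

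Of 20 genes of heat shock and oxidative stress, 1 rose and 0 fell, and adjusted over the list alone 2 rose. hsp-16.2, a small heat shock protein gene, rose by 1.14 (SE 0.18, adjusted p 0.0389), a call that ended in 8 of 15 alternatives. Its adjusted p was 0.0535 with arrays set to a common median and 0.0966 to 0.170 with any array other than L3 replicate 3 left out. The list had an adjusted p of 0.928, with a median of -0.03 and a mean of 0.11 that differed in sign. Of 1247 chemoreceptor genes, 1 rose and 0 fell, and adjusted over the list alone 0 were called. It was sre-3, with 0.94 (SE 0.14, adjusted p 0.0303), at 3.70 ± 0.08 and 4.64 ± 0.18 (SD, n = 3 each), within the range of the background controls, and its call ended with any array other than L3 replicate 3 left out (0.0659 to 0.142). The chemoreceptor list had an adjusted p of 0.667. Its median level of 3.14 lay below the median of the background controls, 3.48, so the array says little about most of its genes. Of 22 genes of vulval, EGF and Notch signalling, 0 were called by limma, also adjusted over the list alone, and 3 had an unadjusted p under 0.05. egl-17 had -0.55 (adjusted p 0.236), and the list had 0.667.

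With the preset correlation, 11 of 29 lists were called, 5 higher and 6 lower. Other splits of the 6 arrays into 3 and 3 called up to 12 lists, and 3 of 10 splits called as many as the real one. The number of list calls therefore does not set the real grouping apart. With an estimated correlation 0 lists were called by camera between the stages, and 2 had an unadjusted p under 0.05. fry, which asks whether a list's genes move one way without comparing them with other genes, called 2 of the 11, the abu genes (adjusted p 0.0492) and the pharyngeal muscle and gland markers.

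**Figure D4:**
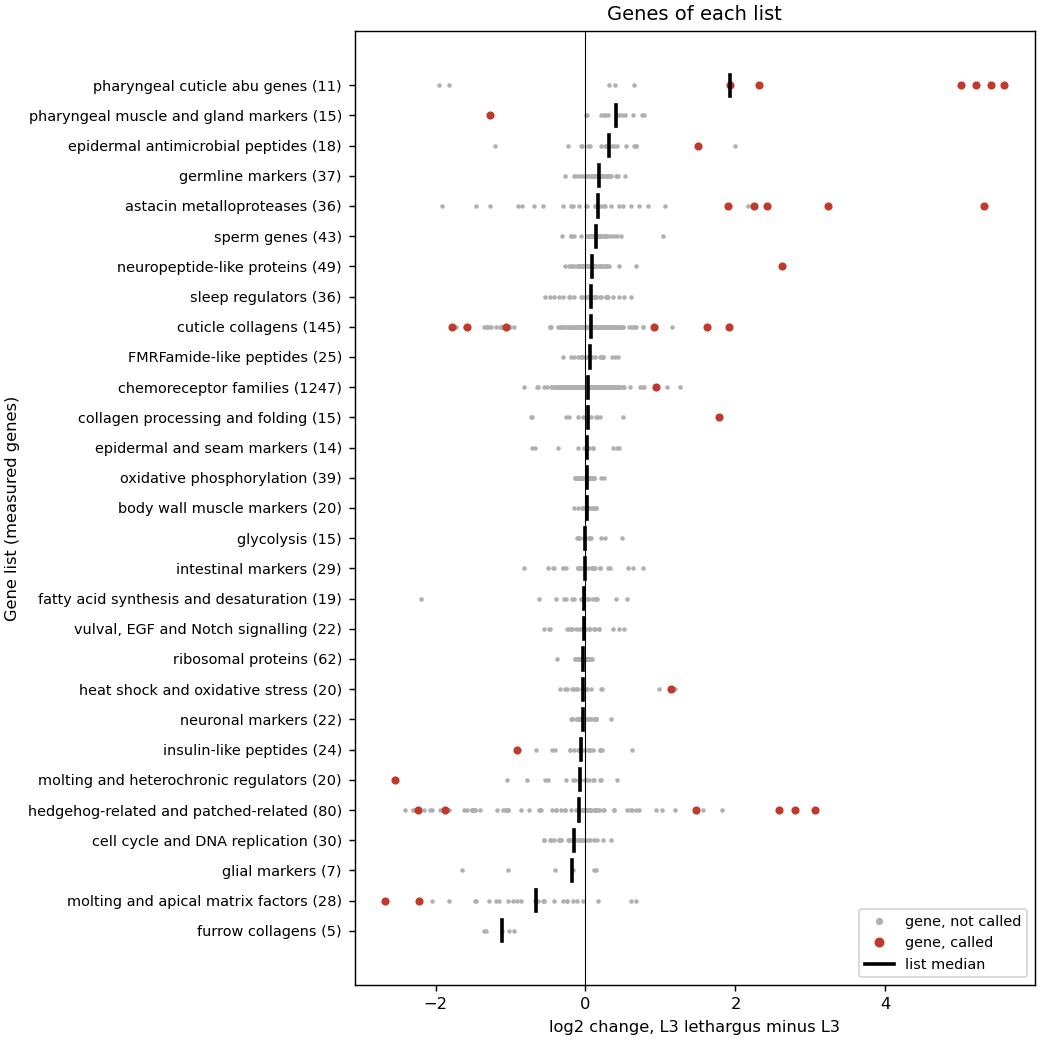
The log2 change of each measured gene, lethargus minus L3 (x axis), in each of 29 gene lists with its number of measured genes (y axis), with called genes in red and black bars at the list medians. The abu genes have the highest median, 1.92, and the furrow collagens the lowest, -1.12.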

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

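The null from the other splits was chosen after the data were seen, as was leaving out marked probe sets for lists other than the cuticle collagens. No result called on 6 arrays turned its direction under any alternative that was run, and calls were lost or gained as follows. On 6 arrays limma gave 170 probe sets higher and 48 lower, 155 and 42 of them at least 2-fold. Leaving out each array in turn gave 75 to 573 higher, 0 to 563 lower, 75 to 444 at least 2-fold higher and 0 to 450 at least 2-fold lower, the highest each time without L3 replicate 3. Array weights gave 262 higher, 231 lower and 207 at least 2-fold lower. A variance trend with robust fitting gave 77 lower and 67 at least 2-fold lower. With p-values from labels permuted over all 10 splits, the real one included, 0 were called higher, 0 lower, 0 at least 2-fold higher and 0 at least 2-fold lower, because that construction allows no adjusted p below 0.1. It gave 2292 probe sets at an unadjusted p under 0.05. With the null taken from the 9 other splits, 168 were higher and 42 lower, and all 210 were among the 218. That overlap was fixed in advance, because the same limma t values were used with another cutoff. These splits mix the stages, so a stage difference adds to the spread within their groups. The replicate number as a block gave 56 higher and 3 lower, 56 and 3 at least 2-fold. The deviations of same-numbered arrays had correlations of 0.26, -0.24 and -0.29, and not every array correlated best with its own number. L3 replicate 3 had 0.46 with lethargus replicate 2, and L3 replicate 2 had 0.32 with lethargus replicate 3. Deviations from means of 3 arrays cannot show whether any pools shared a day or batch. The block removes residual degrees of freedom. A second quantile normalization gave 167 and 45, a common median 164 and 53, and leaving out the dimmest probe sets 171 and 54. Of 38 named genes called on 6 arrays, the call was lost by 38 with labels permuted over all splits, 22 with the block, 19 to 21 with any array other than L3 replicate 3 left out and 0 without that array. It was lost by 3 with the mean of all probe sets, and by 1 each with the null from the other splits, a second quantile normalization and a common median. For the lists, leaving out the dimmest probe sets gave adjusted p-values of 0.0576 for astacins, 0.121 for regulators of molting and timing and 0.0691 for glial markers. Leaving out marked probe sets gave 0.233 for pharynx and 0.0410 for fatty acid synthesis, and 0.0410 for collagen processing, which was then higher where the test on all probe sets pointed down. Array weights gave 0.0855 for astacins and 0.00681 for sperm genes. An estimated correlation gave 0.652 for furrow collagens, 0.469 for molting factors, 0.686 for astacins, 0.652 for the regulators, 0.851 for hedgehog-related genes, 0.469 for abu genes, 0.450 for antimicrobial peptides, 0.839 for glia, 0.450 for pharynx, 0.686 for germline and 0.851 for cell cycle. fry gave 0.403 for furrow collagens, 0.186 for molting factors, 0.186 for astacins, 0.317 for the regulators, 0.782 for hedgehog-related genes, 0.0611 for antimicrobial peptides, 0.726 for glia, 0.317 for germline and 0.726 for cell cycle. With each array left out in turn, adjusted p-values ran from 0.0106 to 0.254 for the regulators, 0.0199 to 0.999 for neuropeptide-like proteins, 0.00756 to 0.254 for glia, 0.000108 to 0.258 for cell cycle, 0.00299 to 0.117 for germline, 0.00388 to 0.280 for astacins, 0.0379 to 0.893 for insulin-like peptides, 8.92e-09 to 0.955 for sperm genes and 0.00567 to 0.951 for ribosomal proteins. Apart from the effect of fewer arrays or probe sets, the cause was not tested. Signal over background limits what can be said of nlp-22, aptf-1, sre-3, vit-4, abu-2 and abu-3, whose means all lie within the range of the background controls. It also limits the size of the rises of nas-1, pqn-71, piit-1, nspb-10, nspb-11, ptr-3, abu-4 and pgp-15 and of the falls of dos-2, hlh-6 and the dimmer probe set of grd-1, with 1 mean within that range. Of the called probe sets, 2.75% have both means below the highest control.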

Other observations

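Families of genes outside the lists were grouped by symbol and tested after the data were seen, as were all other tests of this part except the counts over other splits of the arrays. Of 339 families with at least 5 genes, camera called 8, 4 higher and 4 lower in lethargus. None of the 8 was called with an estimated correlation (adjusted p = 0.995 for each). The bus genes, several of which act in making the glycan coat of the cuticle, were lower with a median log2 change of -1.11 over 14 genes and 1 fall, that of bus-5 (adjusted p = 1.41e-10). The mam genes were lower with a median of -1.35 over 8 genes (1.97e-07), the lipocalin-related lpr genes with -0.86 over 7 (0.00281) and the histone his genes with -0.23 over 26 (7.04e-05). The idpc genes were higher, with 4 of 5 called and a median of 2.00 (5.27e-08). The tyrosinase tyr genes were higher with a median of 0.59 over 5 genes and 1 rise (0.0108), the galectin lec genes with 0.16 over 12 and 1 rise (0.0108), and the nuclear receptor nhr genes with 0.10 over 254 and 3 rises (0.0309). Without L3 replicate 3 the nhr family had 0.133 and the other 7 were called, with medians of -1.42 for bus, -1.81 for mam and 1.62 for idpc.

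Apart from dbd-9 and lips-9, the following genes fall outside the rule for named genes and were chosen after their values were seen. tyr-2 rose by 4.03, lips-17 by 3.64, nspb-12 by 3.46, pqn-54 by 2.76 and idpc-6 by 3.12. The transporter gene pgp-14 rose by 2.56 and 2.79 on its 2 probe sets, and pgp-15, with an L3 mean within the range of the background controls, rose at least 2.12-fold. Of 13 dbd genes, 3 rose and 2 fell: dbd-13, dbd-14 and dbd-20 rose by 1.49, 2.00 and 2.16, while dbd-8 fell by 2.21 and dbd-9 fell by 2.83. Of 16 lips genes, 1 rose and 2 fell, where lips-3 fell by 2.0 and lips-9 fell by 2.37. Neither family was called by camera (adjusted p 0.930 and 0.753).

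L3 replicate 3 lay between the other L3 arrays and the lethargus arrays on the first principal component. If array values were linear in RNA amount, an admixture of lethargus animals or their RNA would give the same lethargus share from rises and from falls. On the linear scale the median share was 45.6% (95% bootstrap interval 38.8 to 52.2) over 573 probe sets called higher without that array. Over 563 called lower it was 74.6% (73.2 to 76.2), and the interval of the difference, 22.8 to 36.2, leaves out 0. The bootstrap drew probe sets of 1 array as if independent, so its intervals do not measure the spread between pools. Amplified and background-corrected values need not be linear in RNA amount, so unequal shares alone cannot decide against an admixture. As the sole difference, an admixture would also move no gene past the lethargus arrays or away from them. However, 32 of 43 sperm genes were highest on that array. Many of them belong to gene families whose members can share probes, which was not examined, so they may not be separate measurements. Of the probe sets called higher without that array, 22.2% had moved away from lethargus there, against 0.71% of those called lower. An admixture beside other differences between the pools was not tested. A 3' bias of the RNA would raise the 3' minus 5' difference of control transcripts there, and 0 of 5 were highest on that array. A later developmental time of these animals may remain as a candidate explanation: on the log2 scale probe sets had moved a median of 57.1% of the way for rises and 59.9% for falls, which an older pool would give, whereas the sperm genes, the rises that moved away and the abu genes, with a median of -1.18 there against the other L3 arrays, go against a pool of intermediate age in which each level moves steadily towards lethargus, and without a time course this cannot be told apart from other differences between the pools.

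The rises of the abu genes could come from probes shared between near-identical abu genes. Probe sequences were not compared, so only the marks of the probe sets bear on this explanation. By those marks it is argued against for abu-10, where 2 of 2 probe sets without a mark for related genes were called higher. For abu-4 it stays open, since 0 of 1 such probe sets was called but that probe set lay within the range of the background controls in both groups, and the rise was on a marked one. For abu-6, abu-8, abu-11 and abu-15 there were 0 such probe sets, and their own rises cannot be told apart from that of a near-identical gene. The design offers the molt itself as a biological explanation for the group, and it was not tested.

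The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 218 probe sets and the highest other split 2, and 1 of 10 splits called as many as the real one. At 2-fold the real split called 197 and the highest other 2, and again 1 of 10 called as many. For the gene lists the real split called 11 and the highest other split 12, and 3 of 10 splits called as many as the real one.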
